A study of Caenorhabditis elegans with 4 samples.

How the data were processed

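The series holds 4 one-colour Affymetrix C. elegans Genome arrays of wild-type young adult hermaphrodites, with 1 array each for the control, BPA, DEHP and NP. Per the labels, total RNA was extracted with RNeasy columns and labelled with biotin. The labelling text names fibroblast cultures as the RNA source, which conflicts with the other label fields, where the source is young adult worms, and the arrays were treated as worm samples. The deposited values are linear probe-set intensity values, 22625 per array, with a mean of about 500 on every array once the lowest and highest 2% of probe sets are left out. They had therefore been scaled to a common trimmed mean. The summary method and software are not given in the sources used here. There are no detection calls in the table and no replicates, and for arrays the number of arrays limits the precision.

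The 77 control probe sets were set aside, which left 22548. Intensities were put on the log2 scale, and each array was shifted to the common median of the 4 arrays, by -0.13 for the control, -0.12 for BPA, 0.017 for DEHP and 0.24 for NP. Values under the pooled 25th percentile (28.3) were set to that floor, and a gene with 1 side at the floor has only a bound on its fold. The platform table assigned 20766 probe sets to 1 gene, 887 to several genes and 895 to none, and the last 2 kinds were left out. For each of 17138 genes the probe set with the highest mean was used, which mattered for 2966 genes with several probe sets. A gene was detected in a comparison if the brighter array was at or above the pooled median (129). Of all probe sets, 6711 are of the _s_ or _x_ type. Gene spans came from the WBcel235 gene table, which held 17085 of the genes. The build used by the authors is not named, so no coordinates are given.

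The comparisons were each exposed array against the control, the exposed arrays against each other, the genes at least 2-fold from the control on the same side on all 3 exposed arrays, and those at least 2-fold from the control and from each other exposed array on a single array. No test was made. Changes of genes and lists are relative to the median detected gene of the comparison. The overlap of all 3 was set beside that of independent lists and 100 simulations of unchanged arrays that shared 1 control, with noise drawn within 20 bins of expression from differences between exposed arrays. Correlations across genes are Pearson's r and Spearman's rho.

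The 34 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed before the data were examined. The lists are those named in the report, from vitellogenins, detoxification enzymes and stress responses to fatty acid metabolism, germline, tissue and receptor genes. Each list's median over detected members was placed among 10000 random lists of the same size, matched in 10 bins of expression. A list stood apart if outside the central 95%, as about 5% of lists of unrelated genes would by chance. Members of a list that move together can place it outside more often without any exposure. The range does not measure the spread between arrays. Lists needed at least 3 detected members. Named genes were the 10 highest and 10 lowest of each comparison with the control, and the 5 highest and 5 lowest between exposed arrays. They had to lie above the floor on both arrays and at or above the pooled 75th percentile (613) on the brighter array, with the same sign under quantile, as-deposited and loess scaling. Further named genes were up to 4 members per list with the largest change, the 10 per direction with the largest smallest change over all 3 arrays, and the 5 per direction and compound for single arrays.

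The alternatives fixed in advance were quantile normalization, values as deposited, loess (span 0.3) against the mean of the arrays, no filter on dim genes, a filter at the 75th percentile, no floor, and the mean over the probe sets of a gene. Chosen after seeing the data were changes centred on the median detected gene, scaling to the median of the brighter probe sets, leaving out the NP array, and a lowess correction for gene span. A control of measurement within an array was the share of 2-fold genes whose other detected probe sets lay on the same side. It was 80.0% of 25 genes for BPA (95% Wilson interval 60.9 to 91.1), 96.7% of 92 for DEHP (90.8 to 98.9) and 92.1% of 127 for NP (86.1 to 95.7).

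The procedure was tested on simulated data with noise taken from the differences of the arrays themselves. Genes and a list were planted only among genes at least 6-fold brighter than the detection level, so the shares called hold for bright genes. All genes planted with a 6-fold difference were called. Of those planted at 3-fold, 100% and 98% were called higher and lower for BPA, 92% and 96% for DEHP and 88% and 90% for NP. Among unchanged genes, 3.58%, 9.52% and 12.0% passed 2-fold in the BPA, DEHP and NP settings. Of 500 unchanged lists of randomly drawn genes with independent noise, 6.6%, 4% and 6% stood apart. These shares do not cover lists whose members move together. A planted list of 20 genes shifted by 0.5 log2 reached percentiles of 100, 100 and 99.05. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.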

Results

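Transcript levels were measured in wild-type young adult hermaphrodites of the nematode Caenorhabditis elegans with 4 one-colour Affymetrix C. elegans Genome arrays, each read at 22625 probe sets. The question posed by the labels and title was which transcripts differ in worms exposed for 24 h to bisphenol A (BPA), di(2-ethylhexyl) phthalate (DEHP) or NP. The labels give the chemicals as abbreviations, and NP is read here as nonylphenol. BPA and NP are phenols and DEHP is a diester of phthalic acid. Each chemical was given at 1/100 of its own 24 h LC50, the median lethal concentration, so the molar doses were not matched. Exposed worms were held at 20 °C in K-medium, a salt solution, without food. The control is labelled untreated, and the labels do not say whether it was held in the medium or fed. They give no exposure time for it, so its age beside that of the exposed worms is not known. The RNA came from worms, not from separated tissues. Lists of tissue genes therefore do not tell expression within a tissue from the share of that tissue. Each group had 1 array, so there are no replicates, no test and no replicate check. The number of arrays limits the precision, and every value describes these 4 arrays only.

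The median deposited intensity was 142 on the control array, 140 on the BPA array, 128 on the DEHP array and 109 on the NP array. After scaling to a common median, the median detected gene lay 0.0099 log2 above the control on the BPA array, 0.16 above it on the DEHP array and 0.38 above it on the NP array. Log2 changes of genes and gene lists are therefore given relative to that median gene, and 2-fold members of lists are counted on that basis. The share of detected genes at least 2-fold from the control was 2.69% for BPA, 8.48% for DEHP and 12% for NP. Relative to the median gene it was 2.71%, 8.54% and 10.3%. In simulated data, 3.58%, 9.52% and 12% of unchanged genes passed 2-fold relative to the median gene. The noise was drawn from these same array differences, which also hold any effect of exposure. The counts of 2-fold genes alone thus do not separate exposure from noise. The deposit holds no detection calls, and a change against an intensity under the detection level of 129 is uncertain in size for any gene named here. A dagger (†) marks genes read by a probe set of the _s_ or _x_ type, whose probes can match several transcripts. Their values, and those of families of close paralogs such as major sperm proteins, histones, vitellogenins, collagens, small heat shock proteins and lysozymes, are uncertain as to the member.

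BPA-exposed worms had higher transcripts of several fatty acid genes than the control. The transcript of acs-2, an acyl-CoA synthetase of mitochondrial fatty acid oxidation, had an intensity of 3943 against 301 in the control, a relative log2 change of 3.70, and its other probe set read 2.13. The hydroxyacyl-CoA dehydrogenase gene hacd-1 (2.88) and the elongase genes elo-6† (2.31) and elo-5† (2.09), which serve branched-chain fatty acid synthesis, were also higher. The lysozyme gene ilys-3 (-2.08), the metallothionein gene mtl-1 (-1.73) and the small heat shock gene hsp-12.6 (-1.59) were lower. Of 8819 genes detected, 117 were at least 2-fold higher and 120 at least 2-fold lower than in the control, or 115 and 124 relative to the median gene.

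The 10 highest genes that met the naming rule also held T22F3.11 (4.37), F46C5.1† (4.07), F21C10.10 (2.37), the bestrophin gene best-1 (2.34), C35C5.8 (2.28) and the aquaporin gene aqp-1 (2.04). The 10 lowest also held Y39B6A.1† (-2.01), the infection response gene irg-4 (-1.91), the cathepsin B-like protease gene cpr-2 (-1.78), gda-1† (-1.53) and F59C6.16 (-1.42). The translation release factor gene erfa-3 read -1.45 on its brightest probe set and 0.11 on its other probe set. The nuclear hormone receptor gene nhr-97 read -1.37 and -0.41.

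The 17 detected genes of fatty acid synthesis, desaturation and elongation had a median of 0.53 on the BPA array, above the central 95% of random lists (-0.13 to 0.17). Of these, elo-5†, elo-6† and the delta-9 desaturase gene fat-5 (1.49) were at least 2-fold higher and none was lower. The 10 detected genes known to rise on fasting had a median of 0.64, with 3 higher members, acs-2 and hacd-1 among them. The 9 genes known to fall on fasting had a median of 0.54, with 2 higher members; 7 of the 9 also belong to the fatty acid synthesis list. Hedgehog-related and patched-related molting genes had a median of 0.45 over 46 members, 3 of them higher and 1, grd-10 (-1.09), lower. Over all 84 members, without the filter on dim genes, that median was 0.21. P-glycoprotein and MRP transporters (median 0.34, n = 13) and cell cycle and DNA replication genes (0.15, n = 27) lay above the random lists without any 2-fold member. In the oocyte and eggshell list (0.22, n = 26), also above, the germline RNA-binding protein gene mex-1† (1.01) was the only 2-fold member.

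Neuronal and glutathione S-transferase genes lay below the random lists on the BPA array. The 38 genes of neurons and neuropeptides had a median of -0.35, with the FMRFamide-like peptide gene flp-10 (-1.32) as the only 2-fold member. The 24 glutathione S-transferases, which conjugate glutathione to reactive compounds, had a median of -0.34 with 2 lower members, among them gstk-2† (-1.01). Muscle genes had a median of -0.15 (n = 24) without a 2-fold member. These lists and those of the preceding paragraph kept their side under every planned setting. Intestine genes (-0.24, n = 12) returned to the random range when the probe sets of a gene were averaged. Nuclear hormone receptors (-0.19, n = 85) had a median of 0.064 when only brighter genes were kept. Sperm genes (-0.25, n = 26), antioxidant enzymes (-0.16, n = 21) and antimicrobial peptides and lysozymes (-0.13, n = 31) were within the random range without the filter on dim genes. Cytosolic ribosomal proteins (0.15, n = 74), above the random lists, were within them after quantile normalization. The manganese superoxide dismutase gene sod-3 (-1.98) and the heat shock genes hsp-16.2 (-3.03) and hsp-16.41 (at least 4.90-fold lower, at the floor) were lower as single genes.

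DEHP-exposed worms showed higher signal for sperm proteins and lower neuronal and muscle transcripts. Of 26 detected sperm genes, 19 were at least 2-fold higher than in the control and none lower, with msp-76† at 2.11 and msp-53† at 2.03. All 19 belong to the msp family, of whose 23 detected members 0 were read by an unshared probe set, and the 3 other detected sperm genes had a median of -0.012. Of 38 neuronal genes, 13 were at least 2-fold lower and none higher, among them the vesicular glutamate transporter gene eat-4 (-1.93) and the synaptotagmin gene snt-1 (-1.85). The elongase genes elo-6† (2.54) and elo-5† (2.27) were higher, as on the BPA array. The transcript of mbug-1 was higher (4.79), with an intensity of 2893 against 93.9, and that of F42A10.7 lower (-5.41), with 38 against 1442. In both the dimmer value lay under the detection level, so the size of the change is uncertain.

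Of 8915 genes detected, 391 were at least 2-fold higher and 365 lower on the DEHP array. Relative to the median gene the numbers were 251 and 510, and with the values as deposited 256 and 533. The 10 highest genes also held the cuticle collagen gene col-101† (4.09), spig-20 (3.64), T13F3.6 (3.45), the folate transporter family gene folt-2† (2.71), ilys-5† (2.55), hpo-6 (2.55), the C-type lectin gene clec-41† (2.54) and C50F7.5 (2.51). The 10 lowest also held hsp-12.6 (-4.22), cpr-2 (-3.88), the hedgehog-related gene grd-10 (-3.76), ilys-3 (-3.64), the collagen gene col-39 (-3.23), the intermediate filament gene ifc-1 (-2.86), C18H7.1 (-2.84), the pharyngeal myosin gene myo-2† (-2.70) and fipr-2 (-2.63). The lysozyme gene lys-7† had an intensity of 14313 against 2749 (2.22).

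The sperm list had a median of 1.56 on the DEHP array, against random lists from -0.17 to 0.16. Below the random lists, neuronal genes had a median of -0.86 and muscle genes one of -0.47 (n = 24), with 4 lower muscle genes, among them the twitchin gene unc-22 (-1.55) and the myosin gene myo-1† (-1.34). The mitochondrial respiratory chain had a median of -0.18 (n = 34). Antioxidant enzymes had one of -0.27 (n = 21), with the glutathione peroxidase genes gpx-6 (-1.39) and gpx-3 (-1.2) among 4 lower members. Above the random lists stood genes known to fall on fasting (0.59, n = 9), with elo-2 (1.27) and fat-5 (1.28) among 4 higher members. Molting genes (0.45, n = 46) held 6 higher members, among them grl-7† (1.70), and 4 lower ones. Cuticle collagens (0.19, n = 75) held 12 higher and 11 lower members. Oocyte and eggshell genes (0.31, n = 26) and fatty acid oxidation genes (0.18, n = 32) were also above, the last with ech-7 (1.60) and hacd-1 (1.59) among its higher members. All lists of this paragraph kept their side under every planned setting.

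Detoxification genes went both ways on the DEHP array. The 28 cytochrome P450 genes had a median of 0.34, with cyp-35C1† (1.44), cyp-35A2 (1.40) and cyp-13A5 (1.34) among 5 higher genes and cyp-33C3 (-1.67) among 3 lower ones. The 26 UDP-glucuronosyltransferases had one of 0.20, with 4 higher, ugt-21 (1.84) among them, and 2 lower. Both medians returned to the random range when dim genes were kept. P-glycoprotein and MRP transporters (0.17, n = 12) were within it, with pgp-1† at 2.07 and pgp-10 at -1.27. So were glutathione S-transferases (-0.072, n = 24), although gstk-2† stood at -2.31. Fatty acid synthesis genes (0.27, n = 17), gut proteases (0.28, n = 17) and cell cycle genes (0.16, n = 27) lay above the random lists, and nuclear hormone receptors (-0.41, n = 89) below them, but not when only brighter genes were kept. Intestine genes (-0.31, n = 12) and cytosolic ribosomal proteins (-0.071, n = 74) were below the random lists, but not after quantile or loess normalization. The insulin-like gene ins-7 (2.12) and the receptor gene nhr-114 (1.46) were higher, and ins-35 (-2.47) was lower.

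NP-exposed worms had lower transcripts of muscle, intestine, neurons and fatty acid synthesis than the control, relative to the median gene. The muscle, intestine and neuronal lists lay below the random lists on all 3 exposed arrays, which share 1 control array. Of 24 muscle genes 7 were at least 2-fold lower, among them myo-2† (-2.70) and unc-22 (-2.57). Of 38 neuronal genes 15 were, among them eat-4 (-2.25). The elongase genes elo-2 (-1.11) and elo-5† (-1.11) lay below the control here and above it on the other exposed arrays. The transcript of nspg-7.2 was higher (4.68), with an intensity of 1774 against 53.4, a control value under the detection level that leaves the size of the change uncertain.

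Of 8940 genes detected, 764 were at least 2-fold higher and 318 lower on the NP array. Relative to the median gene the split turned to 172 higher and 753 lower, and with values as deposited it was 166 and 786. Quantile normalization gave 314 and 448. The ratio of 3-prime to 5-prime control probe sets was highest on the NP array for each of 4 transcripts; for actin it was 1.19 on the control array, 1.22 for BPA, 1.37 for DEHP and 1.88 for NP. The NP changes also ran with gene span, the length of the gene with its introns. Of 5 equal groups of genes by span, the longest minus the shortest had a difference in medians of -0.44 log2 (95% bootstrap interval over genes -0.47 to -0.40), against 0.076 on the BPA array and -0.010 on the DEHP array. After that trend was taken out, a step chosen after seeing the data, 170 genes were higher and 661 lower.

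The 10 highest genes also held mbug-1 (2.53), the fatty acid and retinol binding protein gene far-3† (2.36), H23N18.5 (2.17), Y37A1B.7† (2.07), the hedgehog-related genes grl-15 (1.89) and grl-7† (1.80), mex-1† (1.91) and the kinetochore gene kbp-3 (1.87). The meiotic RING-finger gene zhp-4† read 1.91, and 0.48 on its other probe set. The 10 lowest also held Y39B6A.1† (-3.65), ifc-1 (-3.55), grd-10 (-2.93), the calponin-like gene clik-2 (-2.80, and -1.68 on its other probe set), the collagen genes col-98 (-2.79) and col-39 (-2.59), F46F2.3† (-2.78) and Y54B9A.1† (-2.56). The heat shock gene hsp-12.3 (1.28) and the ferritin gene ftn-1† (1.02) were higher, and mtl-1 stood at 0.81 with an intensity of 5544 against 2438.

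Genes known to fall on fasting had the lowest median of any list on the NP array, -1.11 (n = 9), with acdh-2 (-2.23) and fat-5 (-1.31) among 6 lower members. Intestine genes had a median of -0.90 (n = 12), with the intermediate filament genes ifc-2 (-1.48) and ifb-2† (-1.19) and the intestinal actin gene act-5† (-1.1) among 4 lower members. Neuronal genes had one of -0.73, muscle genes one of -0.70 and fatty acid synthesis genes one of -0.48 (n = 17). Glutathione S-transferases had one of -0.63 (n = 24), with gstk-2† (-1.1) among 6 lower members, and sperm genes one of -0.58 (n = 26). These medians were -0.075 and -0.14 without the filter on dim genes. Gut proteases had one of -0.30 (n = 15), with cpr-4 at -1.77 and cpr-2 at -1.59. These 8 lists and the respiratory chain (-0.071, n = 34) lay below the random lists under every planned setting and after the trend with span was taken out. Cell cycle and DNA replication genes lay above them under all of these (0.33, n = 27).

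Nuclear hormone receptors (-0.46, n = 91) also lay below the random lists on the NP array. Most other NP medians outside the random range depended on the filter on dim genes. P-glycoprotein and MRP transporters had a median of -0.85 (n = 9), with pgp-14† at -2.38 and pgp-10 at -1.46, but one of 0.11 over the brighter genes alone. Genes known to rise on fasting (-0.76, n = 11) and cuticle collagens (-0.28, n = 73) were below the random lists, and molting genes (0.17, n = 45) and cytochrome P450 genes (0.15, n = 28) above them, but not without that filter. The P450 median was also within the random range with values as deposited. In the oocyte and eggshell list, which was within the random range (0.23), car-1 read 1.14 on its brightest probe set and -0.22 and 0.16 on the others. UDP-glucuronosyltransferases (-0.41), fatty acid oxidation genes (-0.019), antioxidant enzymes (-0.045), antimicrobial peptides and lysozymes (-0.10) and cytosolic ribosomal proteins (0.17) were within it as well.

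**Figure D1:**
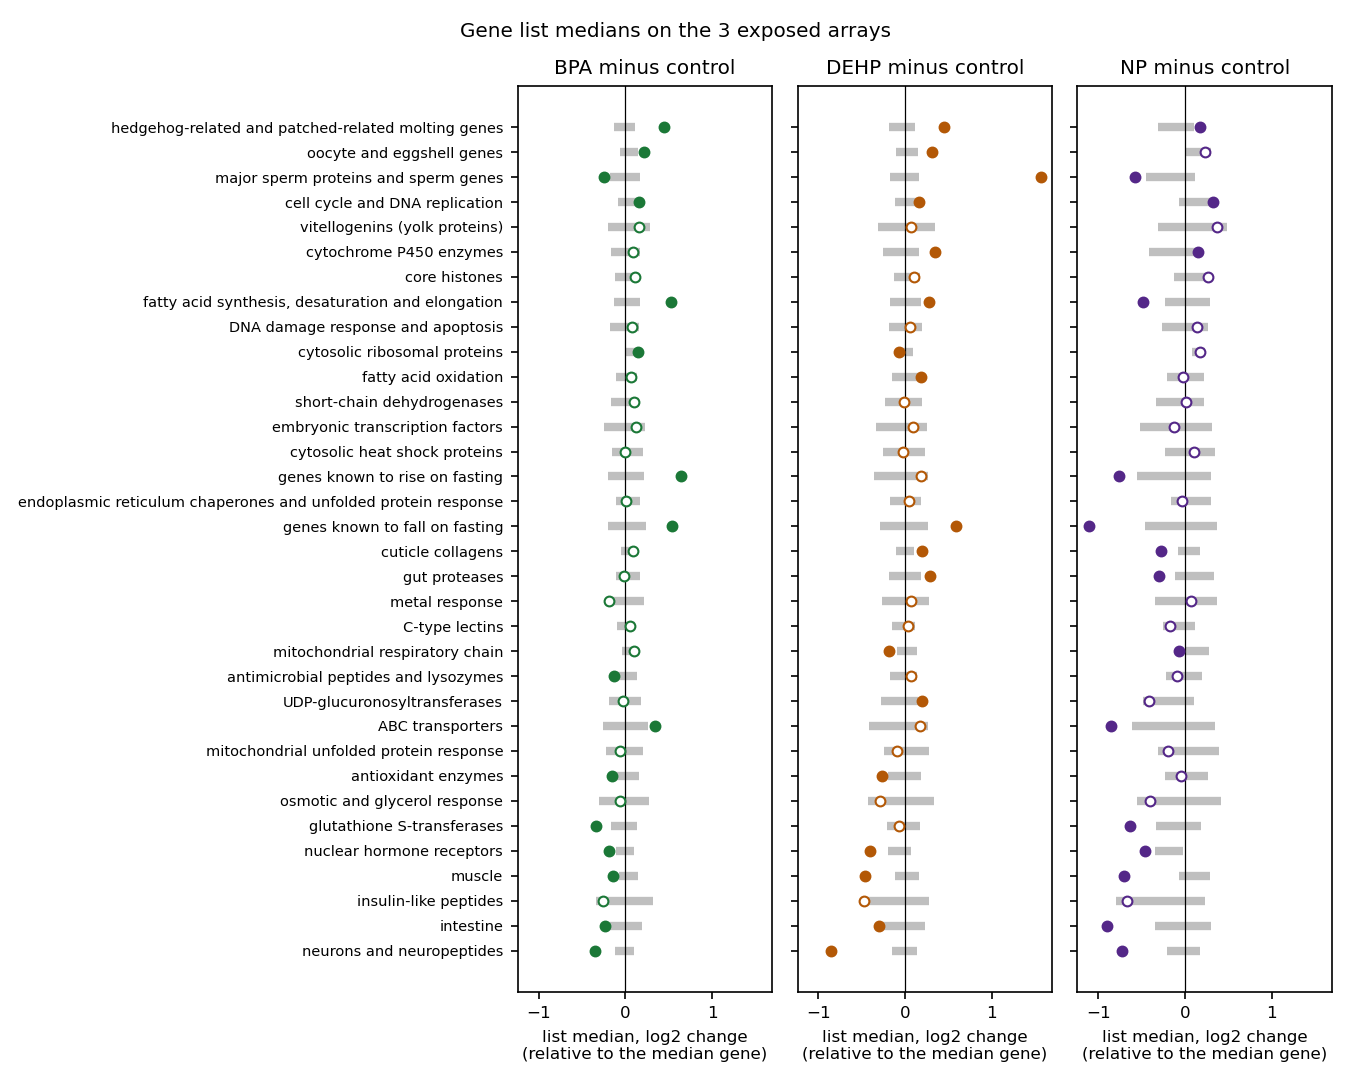
Median log2 change of the 34 gene lists on the BPA, DEHP and NP arrays against the control, relative to the median detected gene, with the central 95% of 10000 matched random lists. The sperm list stood at 1.56 on the DEHP array.

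Some lists lay within the random range on all 3 arrays, and their medians are given for BPA, DEHP and NP in turn. Vitellogenins, the yolk proteins, had 0.16, 0.063 and 0.37, with vit-1 at 1.61 on the DEHP array. C-type lectins had 0.050, 0.029 and -0.18, although clec-52 (-3.66) and clec-82 (-2.69) were lower on the DEHP array. Cytosolic heat shock proteins had -0.0057, -0.030 and 0.10, endoplasmic reticulum chaperones and unfolded protein response genes 0.012, 0.046 and -0.032, and genes of the mitochondrial unfolded protein response -0.065, -0.095 and -0.20. Metal response genes had -0.18, 0.065 and 0.074, DNA damage response and apoptosis genes 0.075, 0.060 and 0.13, and core histones 0.11, 0.10 and 0.26. Embryonic transcription factors had 0.12, 0.085 and -0.13, short-chain dehydrogenases 0.10, -0.010 and 0.0088, insulin-like peptides -0.26, -0.48 and -0.66, and osmotic and glycerol response genes -0.066, -0.29 and -0.41. On the BPA array, further lists within the random range were cytochrome P450 genes (0.086), UDP-glucuronosyltransferases (-0.030), fatty acid oxidation genes (0.062), cuticle collagens (0.089), gut proteases (-0.013) and the respiratory chain (0.10). On the DEHP array, genes known to rise on fasting (0.18) and antimicrobial peptides and lysozymes (0.066) were within it.

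**Figure D2:**
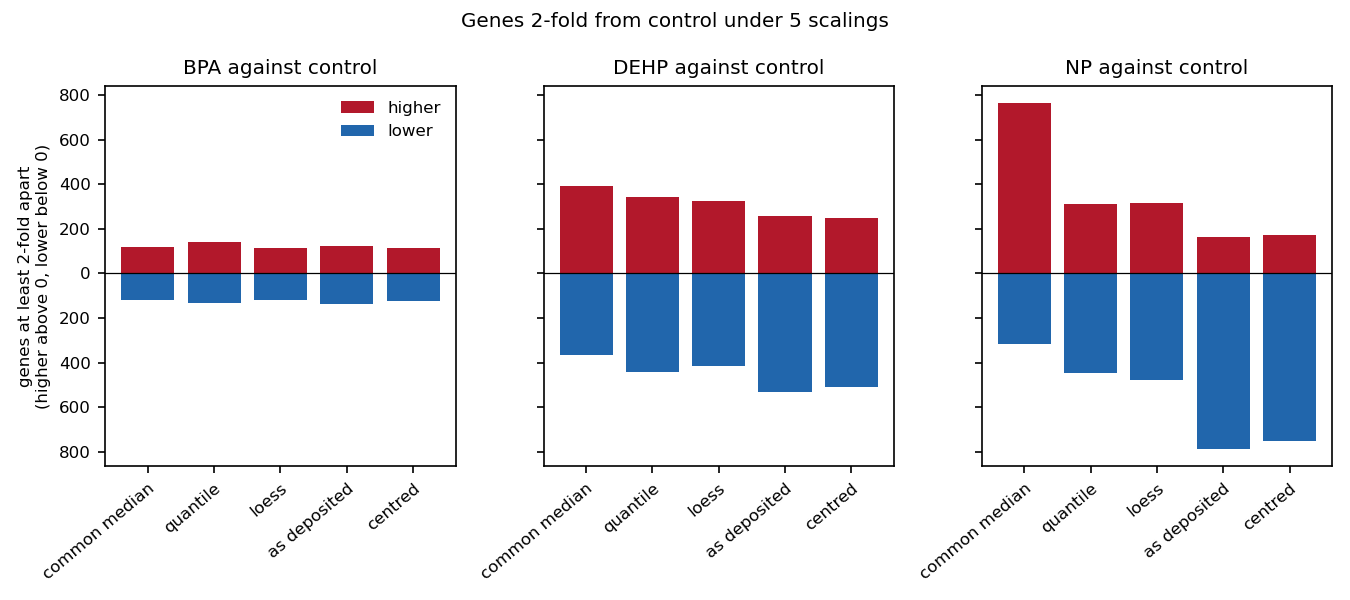
Numbers of genes at least 2-fold higher or lower than in the control for BPA, DEHP and NP under each scaling. The NP numbers turned from 764 higher and 318 lower under the common median to 166 and 786 as deposited.

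Few genes were at least 2-fold from the control on the same side on all 3 exposed arrays. Among 8598 genes detected in all 3 comparisons, 25 were at least 2-fold higher on each exposed array and 31 lower, or 17 and 53 relative to the median gene. The lower genes, with changes for BPA, DEHP and NP, included ilys-3 (-2.08, -3.64 and -2.53), R08F11.4† (-2.60, -2.75 and -4.58), the neuropeptide-like gene nlp-101 (-2.15, -2.2 and -2.12), the aquaporin gene aqp-8 (-1.48, -1.74 and -1.88) and aakg-3 (-1.37, -2.35 and -1.85), a gamma subunit of AMP-activated protein kinase. They also included the Ras-like GTPase gene drn-1 (-1.53, -2.39 and -2.0) and the F-box gene fbxa-216 (-1.40, -1.96 and -2.37). At the floor on the DEHP array, tag-293 was at least 17.5-fold lower, C01G10.6 at least 5.50-fold and F59D6.1 at least 6.44-fold. The higher genes included the lectin gene clec-223 (1.75, 2.2 and 1.56), the collagen genes col-182 (1.82, 2.14 and 2.04) and col-101† (2.31, 4.09 and 1.05), H23N18.5 (1.67, 1.70 and 2.17) and R02F11.1† (1.36, 1.29 and 1.34). Also higher were Y102A11A.5 (1.47, 1.28 and 1.3), F13H8.3 (1.23, 1.48 and 1.22), F53H4.3 (1.82, 1.16 and 1.45), Y38H6C.16 (1.71, 1.14 and 1.51) and amdh-1 (1.31, 1.44 and 1.09).

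The 3 comparisons share 1 control array, so chance values on that array enter all of them. Independent lists of these sizes would share 0.223 higher and 0.188 lower genes, or 0.0240 and 0.644 for the numbers relative to the median gene. In 100 simulations of unchanged arrays with 1 shared control, 31 to 64 genes were higher and 62 to 115 lower in all 3. The numbers found, 25 and 31, or 17 and 53 relative to the median gene, lay below these ranges. Across genes, which are not independent replicates, the changes for BPA and DEHP correlated with a Pearson's r of 0.607 (Spearman's rho 0.609), those for BPA and NP with 0.387 (0.335) and those for DEHP and NP with 0.557 (0.536). The simulated r ran from 0.508 to 0.573, from 0.514 to 0.575 and from 0.515 to 0.570, so only the r for BPA and DEHP lay above its range. The covariance was 0.136 for BPA and DEHP, 0.0941 for BPA and NP and 0.195 for DEHP and NP, against simulated ranges of 0.152 to 0.188, 0.153 to 0.186 and 0.154 to 0.188. The simulated noise came from differences between exposed arrays and so also holds differences between compounds. The 1 control array cannot be split, and all or part of the excess over independent lists may come from it. It enters the gene lists too. Neuronal (-0.35, -0.86 and -0.73 for BPA, DEHP and NP), muscle (-0.15, -0.47 and -0.70) and intestine genes (-0.24, -0.31 and -0.90) lay below the random lists on all 3. Nuclear hormone receptors (-0.19, -0.41 and -0.46) did as well, and molting genes (0.45, 0.45 and 0.17) lay above. For such lists, the control array and a response common to the exposures cannot be told apart. The control array alone does not make the medians of a list differ between the exposed arrays.

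Between exposed arrays, which share medium and lack of food, BPA and DEHP had the fewest 2-fold genes. Of 8853 genes detected, 178 were higher and 242 lower for BPA than for DEHP, or 250 and 187 relative to the median gene. Named by the rule were T22F3.11, F42A10.7, the flavin-containing monooxygenase gene fmo-2, F46C5.1† and best-1, higher for BPA, and mbug-1, spig-20, irg-8, msp-45† and B0024.4, higher for DEHP. The 2 phenols, BPA and NP, were farther apart, with 246 genes higher and 788 lower for BPA, or 591 and 208 relative to the median gene. BPA exceeded NP in acs-2 (3.70 against -0.42), hacd-1 (2.88 against -1.29) and aqp-1 (2.04 against -1.61). NP exceeded BPA in hsp-12.6 (0.69 against -1.59), mtl-1 (0.81 against -1.73), far-3† and Y105C5B.15. For DEHP and NP, 299 genes were higher and 402 lower for DEHP, or 477 and 186 relative to the median gene. DEHP exceeded NP in folt-2†, T05E12.6†, Y39B6A.1†, T13F3.6 and irg-8 (1.99 against -2.06), and NP exceeded DEHP in hsp-12.6, F42A10.7, nspg-7.2, mtl-1 and the neuropeptide-like gene nlp-39 (1.29 against -1.92). The NP array also had the highest ratios of control probe sets, and its changes ran with gene span. With that trend taken out, genes 2-fold apart relative to the median gene fell from 799 to 710 for BPA and NP. They fell from 663 to 606 for DEHP and NP and from 437 to 428 for BPA and DEHP. BPA and NP stayed farthest apart, but for NP the quality of the array and the compound cannot be told apart. With 1 array per compound and doses that were not matched, these differences are not attributed to the compounds' structure.

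Some genes stood at least 2-fold from the control and from each other exposed array on a single array. There were 15 such genes higher and 13 lower for BPA, 71 and 53 for DEHP, and 84 and 59 for NP. Relative to the median gene the numbers were 18 and 6, 61 and 47, and 12 and 159. For BPA the higher genes included acs-2, best-1, C35C5.8 and fmo-2 (1.48). The lower ones included the glucuronosyltransferase gene ugt-12† (-1.75), ttr-23 (-1.45), K10B3.1 (-1.29) and slc-30A9, which was at least 5.66-fold lower. DEHP had clec-41†, C50F7.5, T05E12.6† (2.08), msp-76† and msp-53† higher, and F42A10.7, hsp-12.6, clec-52, F19C7.2 (-2.86) and clec-82 lower. NP had kbp-3, K10B3.1 (1.73), W10G11.2 (1.67), C09E7.4 (1.45) and nlp-39 higher. It had scl-14 (-3.13), the ribosomal RNA gene rrn-3.1 (-2.86), nssp-41 (-2.46), clec-174† (-2.23) and H10E21.5, at least 8.96-fold, lower.

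**Figure D3:**
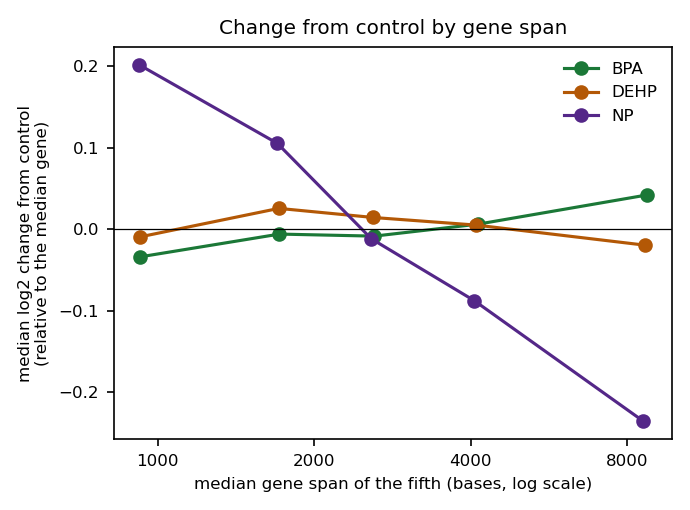
Median log2 change from the control in 5 equal groups of detected genes by gene span, relative to the median detected gene. The NP medians ran from 0.20 in the shortest group to -0.24 in the longest.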

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

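The tests of the scaling, of younger animals and of the trend with gene span taken out were chosen only after the result was seen. The differences between groups below were not tested, since each group had 1 array.

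Some control probe sets outside the gene comparisons showed 3-prime to 5-prime ratios above those of the control array, where the ratios were 1.19 for actin, 1.63 for catalase, 0.951 for GAPDH and 6.66 for ubiquitin. For actin the ratio was 1.22 on the BPA array, 1.37 on the DEHP array and 1.88 on the NP array. For catalase it was 1.82 for DEHP and 3.38 for NP, but lower than the control for BPA at 1.44. For GAPDH it was 1.19 for NP, but lower than the control for BPA at 0.832 and for DEHP at 0.934. For ubiquitin it was 8.28 for BPA, 8.01 for DEHP and 8.98 for NP. The NP array had the highest ratio for each of the 4 transcripts.

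Several gene lists lay above the random lists on 1 exposed array and below them on another. Genes known to rise on fasting had medians of 0.64 for BPA and -0.76 for NP, and those known to fall 0.54 for BPA, 0.59 for DEHP and -1.11 for NP. Fatty acid synthesis genes had 0.53, 0.27 and -0.48. P-glycoprotein and MRP transporters had 0.34 for BPA and -0.85 for NP. Sperm genes had -0.25, 1.56 and -0.58 for BPA, DEHP and NP. Ribosomal proteins had 0.15 for BPA and -0.071 for DEHP. Cuticle collagens had 0.19 for DEHP and -0.28 for NP, and gut proteases 0.28 and -0.30. Under every planned setting, both sides were kept by genes known to fall on fasting, by fatty acid synthesis genes for BPA and NP, and by sperm genes for DEHP and NP. The other contrasts lost at least 1 side: the transporters for NP turned to 0.11 over the brighter genes, the ribosomal proteins were within the random range after quantile normalization for BPA (0.0039) and DEHP (-0.044), and without the filter on dim genes the genes known to rise on fasting for NP (-0.059), cuticle collagens for NP (-0.016) and gut proteases for DEHP (0.17) were within the random range. Single genes at least 2-fold from the control in opposite directions, relative to the median gene, numbered 3 for BPA and DEHP, 9 for BPA and NP and 23 for DEHP and NP.

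On the NP array 764 genes were higher and 318 lower, but with values as deposited only 166 were higher and 786 lower. Quantile normalization (314 and 448) and loess (316 and 477) also gave more lower than higher genes. The excess of higher genes thus depended on scaling to a common median. Long genes lay lower, with a difference in medians of -0.44 between the longest and the shortest of 5 groups by span. A loss of long transcripts predicts this. After the trend was taken out, 831 genes were 2-fold from the control, 727 of them among the 925 before. The trend removed was small beside 2-fold, with medians from 0.20 in the shortest group to -0.24 in the longest. Gene span also counts introns, so this step does not decide whether such a loss is the cause. Degradation of the RNA was to leave the probe sets of a gene in poorer agreement, and 92.1% of NP genes had other probe sets on the same side. That met the bound set against it, but the bound rested on 25 BPA genes with an interval of 60.9 to 91.1, and the ratios above were highest on the NP array, so degradation and exposure cannot be told apart. An effect of NP stays open and was not tested.

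On the DEHP array the 26 detected sperm genes had a median of 1.56. The 23 major sperm protein genes among them had a median of 1.61 and 0 of them were read by an unshared probe set, while the 3 other detected members had one of -0.012 (random lists -0.86 to 0.58), so 1 signal shared between paralogs may be counted many times. For younger animals, lower oocyte, eggshell and vitellogenin transcripts were predicted, and the oocyte and eggshell list lay above the random lists at 0.31, while vitellogenins (0.063) lay within them. Cuticle collagens (0.19) lay above them on this array only, which goes with younger animals. Their members were split, however, with 12 higher and 11 lower. With averaged probe sets the collagens lay above the random lists for BPA too (0.13). Molting genes (0.45) lay above them for BPA (0.45) and NP (0.17) too, where sperm genes lay below them (-0.25 and -0.58). Of these, molting genes for NP (0.082) and sperm genes for BPA (-0.031) were within the random range without the filter on dim genes. Age and exposure cannot be told apart from these lists. More sperm, or an effect of DEHP, stays open and was not tested.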

How the results depend on the processing

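The tests with changes centred on the median detected gene, with arrays scaled to the median of the brighter probe sets, with the trend on gene span taken out and without the NP array were chosen only after the result was seen. No leave-one-out and no paired analysis was possible because each group had 1 array. Under the reported setting, higher and lower genes numbered 117 and 120 for BPA, 391 and 365 for DEHP and 764 and 318 for NP, those shared by all 3 arrays 25 and 31, and those of a single array 15 and 13 for BPA, 71 and 53 for DEHP and 84 and 59 for NP. Genes 2-fold apart numbered 420 between BPA and DEHP, 1034 between BPA and NP and 701 between DEHP and NP. Of 50 list medians outside the random range, 29 stayed outside it and on their side of 0 under every planned setting. Without the floor every count, list median and correlation kept its side or stayed within 1.5 times. Except where a construction is named, the cause was not tested.

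Without the filter on dim genes, more genes entered by construction. Higher and lower genes numbered 392 and 344 for BPA, 681 and 657 for DEHP and 998 and 594 for NP, shared ones 61 and 68 and those of a single array 81 and 46 for BPA, 161 and 91 for DEHP and 167 and 99 for NP. Genes 2-fold apart numbered 1050 between BPA and DEHP, 1678 between BPA and NP and 1251 between DEHP and NP. The correlation for BPA and DEHP was 0.501, and other probe sets lay on the same side for 52.0% of BPA genes and 75.4% of DEHP genes. For BPA antioxidant enzymes (-0.044), antimicrobial peptides (0), sperm genes (-0.031) and nuclear hormone receptors (0), for DEHP cytochrome P450 genes (0), UDP-glucuronosyltransferases (0.11), gut proteases (0.17) and nuclear hormone receptors (0) and for NP cytochrome P450 genes (0.086), genes known to rise on fasting (-0.059), cuticle collagens (-0.016), molting genes (0.082) and nuclear hormone receptors (-0.016) came to lie within the random range. For BPA osmotic response (0.36) and embryonic transcription factors (0.17), for DEHP insulin-like peptides (-0.21) and for NP core histones (0.61) and insulin-like peptides (-0.24) came to lie outside the random range. For DEHP ribosomal proteins (0.089) and for NP the respiratory chain (0.29) changed side of 0. These 2 lists still lay below the random lists (0.12 to 0.27 and 0.38 to 0.66), and nearly all their members were detected before, so the change of side comes by construction from the median gene, which lay at 0 for DEHP and 0.016 for NP here. Nuclear hormone receptors and their random lists were all at the value of genes without any change, with 61 to 66 of 259 genes at the floor on both arrays, so this setting says nothing about them.

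With the stricter filter fewer genes were counted by construction. Their numbers were 47 and 30 for BPA, 161 and 101 for DEHP and 489 and 91 for NP, with 8 and 10 shared, 4 and 3 for BPA, 22 and 14 for DEHP and 37 and 20 for NP on a single array, and 164 between BPA and DEHP, 586 between BPA and NP and 318 between DEHP and NP. Other probe sets lay on the same side for 100% of DEHP genes. For BPA antioxidant enzymes (-0.047) and sperm genes (-0.047), for DEHP UDP-glucuronosyltransferases (0.26), fatty acid synthesis (0.16), cell cycle genes (0.12), gut proteases (0.12) and nuclear hormone receptors (-0.13) and for NP cytochrome P450 genes (0.33) came to lie within the random range. For BPA metal response (-0.26), fatty acid oxidation (0.17), core histones (0.20) and DNA damage response (0.24), for DEHP genes known to rise on fasting (0.55), antimicrobial peptides (-0.22) and C-type lectins (0.34) and for NP antimicrobial peptides (-0.45) came to lie outside the random range. For BPA nuclear hormone receptors (0.064) and for NP P-glycoprotein and MRP transporters (0.11) changed side of 0.

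With values as deposited the numbers were 125 and 136 for BPA, 256 and 533 for DEHP and 166 and 786 for NP, with 17 and 57 shared and 18 and 8 for BPA, 67 and 50 for DEHP and 13 and 165 for NP on a single array. The lack of rescaling lowers the NP array by construction. For BPA antimicrobial peptides (-0.11) and for NP cytochrome P450 genes (0.10) came to lie within the random range.

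Quantile normalization gave 141 and 133 for BPA, 342 and 441 for DEHP and 314 and 448 for NP, 18 and 12 for BPA, 62 and 58 for DEHP and 23 and 79 for NP on a single array, and 430 between BPA and DEHP, 678 between BPA and NP and 593 between DEHP and NP. For BPA antioxidant enzymes (-0.14) and ribosomal proteins (0.0039) and for DEHP ribosomal proteins (-0.044) and intestine genes (-0.24) came to lie within the random range. For DEHP insulin-like peptides (-0.43) came to lie outside the random range.

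Loess gave 115 and 121 for BPA, 325 and 415 for DEHP and 316 and 477 for NP, and 18 and 12 for BPA, 64 and 56 for DEHP and 26 and 101 for NP on a single array. For BPA antioxidant enzymes (-0.14), antimicrobial peptides (-0.11) and ribosomal proteins (0.034), for DEHP ribosomal proteins (-0.072) and intestine genes (-0.24) and for NP cytochrome P450 genes (0.20) came to lie within the random range.

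Averaging the probe sets of a gene gave 106 and 113 for BPA, 358 and 334 for DEHP and 696 and 296 for NP. For BPA antioxidant enzymes (-0.047), antimicrobial peptides (-0.086), ribosomal proteins (0.10) and intestine genes (-0.18) came to lie within the random range. For BPA cuticle collagens (0.13), for DEHP insulin-like peptides (-0.48) and for NP osmotic response (-0.58) came to lie outside the random range.

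Among the tests chosen later, centring gave 115 and 124 for BPA, 251 and 510 for DEHP and 172 and 753 for NP, with 17 and 53 shared and 18 and 6 for BPA, 61 and 47 for DEHP and 12 and 159 for NP on a single array. Scaling to the brighter probe sets gave 136 and 127 for BPA, 261 and 517 for DEHP and 227 and 635 for NP, with 18 and 48 shared and 17 and 7 for BPA, 63 and 56 for DEHP and 22 and 131 for NP on a single array. Without the NP array, 47 and 63 genes were higher and lower on both remaining exposed arrays, where by construction fewer arrays must meet the threshold.

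With the trend on gene span taken out, the numbers were 115 and 122 for BPA, 259 and 497 for DEHP and 170 and 661 for NP, with 15 and 54 shared and 20 and 7 for BPA, 60 and 44 for DEHP and 11 and 130 for NP on a single array. For BPA antioxidant enzymes (-0.12), antimicrobial peptides (-0.074) and sperm genes (-0.16), for DEHP cell cycle genes (0.12) and for NP cytochrome P450 genes (0.14) came to lie within the random range. For BPA core histones (0.20) and for NP vitellogenins (0.50), antimicrobial peptides (-0.26), oocyte and eggshell genes (0.23) and DNA damage response (0.29) came to lie outside the random range.

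Among the changes of named genes, 22 moved without the filter on dim genes, 13 under loess, 9 under quantile normalization, 7 with averaged probe sets, 2 under the stricter filter and 1 with values as deposited, and none changed side. With changes not centred 22 moved, and with the trend on gene span taken out 5. Signal over background limits dim genes, since values under the floor of 28.3 give a bound only.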

Other observations

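The test of the noise of the shared control array was chosen only after the result was seen. Genes at least 2-fold from the control on all 3 exposed arrays numbered 25 higher and 31 lower, or 17 and 53 relative to the median gene. The mean covariance of the changes was 0.142, below the 0.154 to 0.187 of simulated unchanged arrays with 1 shared control. By pair, the covariance for DEHP and NP (0.195) lay above its highest simulated value (0.188), and that for BPA and DEHP (0.136) and for BPA and NP (0.0941) below the lowest (0.152 and 0.153). The simulated noise also holds differences between compounds, so noise of the shared control array and a response common to the exposures cannot be told apart.

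A second hypothesis was that the lack of food during the exposure may set the exposed arrays apart. It predicted that genes known to rise on fasting lie above 0 and those known to fall lie below 0, and in 3 of 3 comparisons at least 1 of these lists did otherwise. The fasting-rise list lay at 0.64 for BPA and 0.18 for DEHP and the fasting-fall list at -1.11 for NP, on the predicted side. The fasting-fall list lay at 0.54 for BPA and 0.59 for DEHP, above the random lists under every planned setting. If the control was fed, that argues against lack of food alone on the BPA and DEHP arrays. The labels do not say whether it was fed, and with an unfed control these lists say nothing about food. The fasting-fall list also holds only 9 genes, 7 of them shared with the fatty acid synthesis list. Each exposed array held both lack of food and a compound, and these lists are not the genes shared by all 3. Lack of food and exposure therefore cannot be told apart as the cause of the shared genes. The NP failure rests on the fasting-rise list (-0.76), which was within the random range without the filter on dim genes (-0.059).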
